A study of Mus musculus with 3 samples.

How the data were processed

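Hi-C, which ligates and sequences DNA fragments that lie close together in the nucleus, was performed on fore- and hindlimb buds of wild-type mouse embryos at day E11.5. There were 3 libraries, all of 1 group. Per the labels' protocols they were technical replicates made from a single pool of tissue. The protocol text counts 8 embryos in this pool and the series' design text counts 10. Every library also carries a cell type label that names G4 embryonic stem cells beside a tissue label that names limb bud, and the tissue label was followed. Per the labels' protocols, chromatin was fixed with formaldehyde, cut with DpnII and filled in with a biotinylated nucleotide.

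The data used here were 1 deposited table for all 3 libraries together, with 1 line per chromatin domain. Per the submitters' processing notes, Juicer and BWA were used and the genome build was mm9. Their versions are not given in the sources used here. Per the name of the deposited table, domains came from TopDom, a quantile threshold of 0.98 was applied and a random forest classified the domains at a threshold of 0.5. Per the file headers, each domain has a class, a direction, a probability, an imbalance score, an imbalance difference score and a cosine score. The deposited probability is a fraction between 0 and 1, in steps of 0.01 in every line that has one. How the authors computed the imbalance, imbalance difference and cosine scores is not given in the sources used here, so they were used only to rank and describe domains within the table. Domain edges lie on a grid of 25 kb, and a second pair of tuned edges lies on a grid of 10 kb. How the tuning was done, and which side of a domain a direction of TRUE or FALSE names, is not given in the sources used here. Whether contacts of the 3 libraries were pooled before or after domain calling is not given either. No values per library were used, and the sequencing depth and the number of contacts behind each domain are unknown. Neither an SD between libraries nor a counting error of the Hi-C contacts can therefore be attached to any value.

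Coordinates are those of the deposited table in mm9, with starts written counting from 1. The only gene table at hand belongs to another build and its coordinates were not set against these, so the planned comparisons with gene starts, gene lists and CTCF motifs were not made, and no domain is assigned to a gene. The table covers chromosomes 1 to 19, so the planned comparison of chromosome X with the autosomes was not made.

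Class 1 was taken as the stripe class, since every class 1 domain has a probability of 0.5 or more and no class 0 domain does. Shares of domains are given with 95% Wilson intervals, densities per Mb with exact Poisson intervals, and differences between groups of domains with 95% bootstrap intervals over domains (5000 draws). These intervals and p-values treat single domains as the unit, except that the binomial tests of class 1 pairs treat pairs as the unit. All measure the spread within 1 table, not between embryos or libraries. Direction was tested with exact binomial tests against an equal split. Differences in length, edge position and neighbour length were tested with two-sided permutation tests (100000 permutations, 10000 in the alternatives and 2000 where a chromosome was left out). Neighbouring pairs were tested by permuting classes within chromosomes, and shares between chromosomes or length groups by permuting classes over all domains. Benjamini-Hochberg adjustment covered 15 tests. The 2 tests of single length groups and the 2 tests of a difference between classes in the effect of direction were outside this family. So were the tests of medians of edge positions and neighbour lengths. The p-values of all these tests are unadjusted. The planned overlap of class 1 domains was set against 1000 random placements.

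The choices of direction, length, overlap and density tests and of the regions to name were made before the data were examined. The regions named are the 5 class 1 domains with the highest probability (ties by position), the 5 longest, the 5 intervals of 1 Mb holding the most class 1 domain midpoints, and the chromosomes of highest and lowest density. The difference of mean lengths and the differences of median edge positions and median neighbour lengths were added after the table had been seen. So were the tests of neighbouring pairs, length groups, gaps, edges and neighbour lengths, and the split of class 1 by imbalance at 0.2. The alternatives tried were higher probability thresholds, merging of domains, other length summaries, tuned edges, the low-imbalance domains moved to class 0 and each chromosome left out in turn.

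The permutation tests of mean edge positions, neighbouring pairs, mean lengths and chromosome shares were tested, with fewer permutations, on 50 simulated tables built on the real domain positions. The tests of neighbour lengths, gaps, length groups, medians and differences between classes were not simulated. A shift of 10 kb between directions in class 1 was called in 50 of 50 tables, with a mean estimate of -9.90 kb for a true difference of -10 kb, and shuffled directions were called in 3 of 50. Strong clustering of classes, simulated by cutting a running sum of random values over 3 domains in a row, was called in 50 of 50 tables. Shuffled classes were called in 3 of 50. Weaker clustering and smaller shifts were not simulated, so how often they would be missed is unknown. Shuffled labels carry no dependence between adjacent domains, so its effect on the tests was not examined. Shuffled classes were called in 3 of 50 tables by the test of mean lengths and in 3 of 50 by the chromosome test. Labels were shuffled much as the tests permute them, so call rates near the threshold were given in advance. The work was done with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.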

Results

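Chromatin domains of the developing mouse limb were examined for one-sided contact structures. Hi-C was performed on wild-type limb buds at embryonic day E11.5, when the limb skeleton is being patterned. The design describes a search for architectural stripes, lines of enriched contact that run from one anchor across a domain and that are usually explained by cohesin reeling in chromatin from a fixed point. All 3 libraries belonged to 1 group, so no condition was compared with another. The comparisons are between domains called with and without a stripe, between the 2 directions a domain can have, and between chromosomes. The authors' values are given per domain for all libraries together, so there is no replicate error, and the depth is unknown.

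The table held 4124 domains on 19 chromosomes, covering 2211 Mb of the mm9 genome. Domains were between 50 kb and 6325 kb long and none overlapped another. Of the 4105 neighbouring pairs on a chromosome, 3084 shared a boundary and 1021 were separated by a gap of unassigned sequence, with a median of 125 kb. On 12 chromosomes the first domain began at 3 Mb.

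Stripes were called in 1448 domains (class 1), which is 35.1% of all domains (95% Wilson interval 33.7 to 36.6%). These domains covered 731 Mb, or 33.1% of the sequence in domains. The random forest probability was 1.00 for 311 domains and 0.00 for 299, and 439 domains (10.7%) lay between 0.4 and 0.6. Among class 1 domains, 668 had a probability of 0.9 or more and 166 had one below 0.6. Because ties at 1.00 were ordered by position, the 5 domains named for the highest probability all lie on chromosome 1. They span 13125001 to 13700000, 15000001 to 15750000, 21400001 to 22425000, 42850001 to 43150000 and 83725001 to 84700000. The fourth had direction FALSE and an imbalance score of 1.75, and the other 4 had direction TRUE and imbalance scores between 0.785 and 0.965.

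Class 1 domains had a median imbalance score of 0.704 (quartiles 0.566 and 0.955, n = 1448), against 0.203 (quartiles 0.101 and 0.325, n = 2674) in class 0. The median cosine score was 0.579 in class 1 and 0.695 in class 0. A test of these differences was not made, because the call could have been built from these scores. The class 1 share did not rise steadily with imbalance. Over 10 groups of equal size ordered by imbalance, it was 0 of 413 domains in the lowest and 22.1% (91 of 412) in the next, between 0.0588 and 0.116. It was 1 of 412 in the third, and 0 of 1236 in the next 3, between 0.174 and 0.405. A count of 0 of 1236 allows a share of up to about 0.243%, taken as 3 counts over the number of domains and not as a Wilson limit. The class 1 share was 29.9% (123 of 412) in the group after these 3 and 99.7% (1233 of 1237) in the highest 3. Below an imbalance of 0.2 there were 92 class 1 domains, with imbalance scores from 0.0683 to 0.118, and the other 1356 began at 0.429. These 92 low-imbalance domains made up 6.35% of class 1, and their probabilities ran from 0.50 to 0.62 with a median of 0.51, against a median of 0.89 in the other 1356. The domains with the highest probability in this set were on chromosome 4 from 97225001 to 97450000 and on chromosome 14 from 123300001 to 123750000, both at 0.62. Probability was raised at low imbalance beyond these 92. Its median was 0.37 in the 480 domains below their imbalance range, all class 0. It was 0.13 in the 1732 domains between that range and the other class 1 domains. The 92 were thus the part of a wider rise in probability at low imbalance that reached the threshold.

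**Figure D1:**
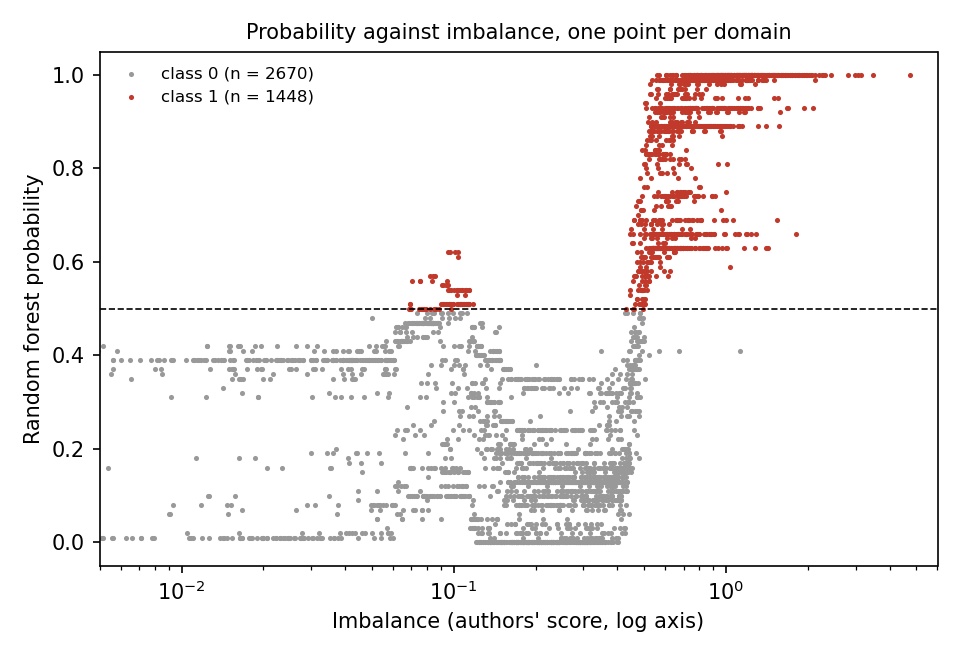
Each point is a domain, with the authors' imbalance score on a log axis (no unit) against the random forest probability; the dashed line is the threshold of 0.5, red points are class 1 and grey points class 0. Of 4124 domains, 30 lie left of the axis start at 0.005 and 6 with an imbalance of 0 or infinity are not drawn. Class 1 domains form a main group above an imbalance of 0.429 and a second group of 92 between 0.0683 and 0.118. The probabilities of these 92 run from 0.50 to 0.62. Probability is also raised beside this second group, with a median of 0.37 in the 480 class 0 domains below its range.

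Class 1 domains occurred on all 19 chromosomes at an overall density of 0.60 per Mb of spanned sequence (exact 95% Poisson interval 0.570 to 0.632). Chromosome 9 had the highest density, with 95 class 1 domains and 0.785 per Mb (interval 0.635 to 0.960). Chromosome 15 had the lowest, with 49 domains and 0.488 per Mb (interval 0.361 to 0.645). As a share of domains, class 1 ranged from 28.3% on chromosome 13 (60 of 212) to 41.9% on chromosome 9 (95 of 227). Over all 19 chromosomes this variation did not exceed chance (permutation test, p = 0.248, adjusted p = 0.372).

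**Figure D2:**
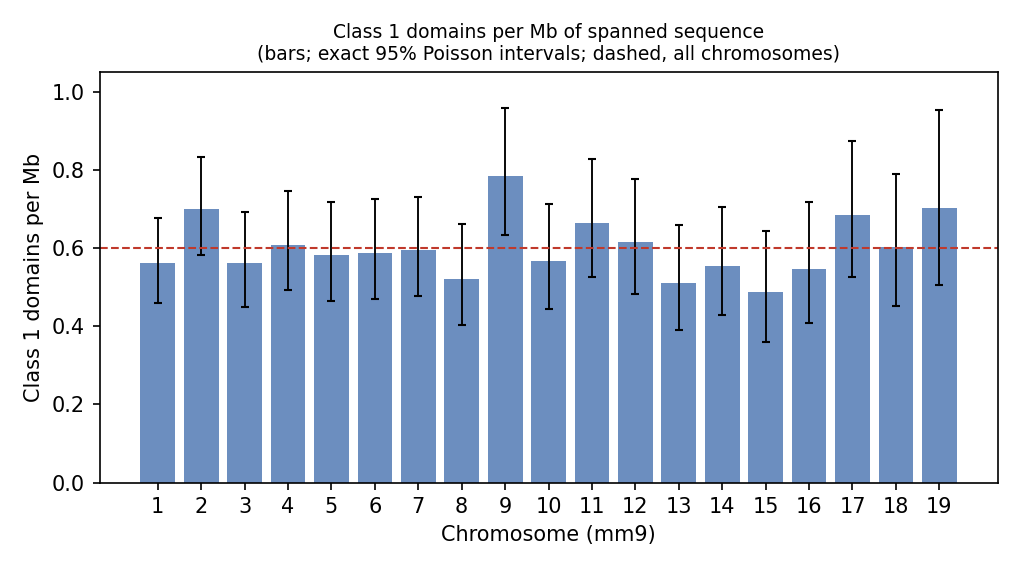
Bars give class 1 domains per Mb on each mm9 chromosome, counted over the span from the first to the last domain; lines are exact 95% Poisson intervals and the dashed line is the density over all chromosomes, 0.60 per Mb. The bars run from 0.488 on chromosome 15 to 0.785 on chromosome 9.

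By midpoints per interval of 1 Mb, the densest stretch of class 1 domains lay on chromosome 9 between 108 and 110 Mb. Such counts also rise where domains are short, and how high a maximum random assignment would give was not computed. Both intervals of 1 Mb in the chromosome 9 stretch held 4 domain midpoints, and all of these domains were class 1. The first interval had 3 domains of direction TRUE and 1 of FALSE, and the second had 1 of TRUE and 3 of FALSE. No other interval held more than 3, and 25 intervals held 3. The next intervals by position were on chromosome 1 between 24 and 25 Mb (3 of 3 domains in class 1), on chromosome 2 between 58 and 59 Mb (3 of 4) and on chromosome 3 between 50 and 51 Mb (3 of 4). The longest runs of class 1 domains with shared boundaries had 5 members. These were on chromosome 5 from 50750001 to 54525000, on chromosome 7 from 12125001 to 15000000 and on chromosome 12 from 102175001 to 104325000, and they were singled out after their values were seen.

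Class 1 domains were next to each other about as often as random assignment gave. Both members were class 1 in 380 of the 3084 pairs that shared a boundary, against a mean of 379 (central 95% 351 to 407) when classes were shuffled within chromosomes (permutation test, p = 0.945). Merging class 1 domains that shared a boundary left 1068 regions, of which 780 were single domains. No class 1 domain overlapped another, against 44.2% on average when the domains were placed at random along their chromosomes. The domains of the table never overlap, so this comparison was fixed by how domains were called. Class 1 domains bordered a gap on at least one side more often than class 0 domains, in 45.5% against 40.0% of cases. This difference of 5.49 percentage points (95% interval 2.35 to 8.61) passed the permutation test (p = 0.00054, adjusted p = 0.00162). The shuffling of classes ignored which domains border gaps, so its mean of 379 pairs may be too high and some clustering could be missed.

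The 2 directions were about equally frequent. Class 1 held 704 domains of direction TRUE and 744 of direction FALSE, which is 48.6% TRUE (95% Wilson interval 46.1 to 51.2%; exact binomial test, p = 0.305, adjusted p = 0.416). Resampling whole chromosomes gave an interval of 46.3 to 51.0%. Class 0 held 1323 TRUE and 1353 FALSE domains (49.4% TRUE, exact binomial test, p = 0.575). FALSE outnumbered TRUE on 13 chromosomes and TRUE outnumbered FALSE on 6. Of the 380 neighbouring class 1 pairs, 209 had unlike directions and 171 had like directions, 77 both TRUE and 94 both FALSE. Pairs of unlike direction made up 55.0% (95% interval 50.0 to 59.9%), which did not pass the exact binomial test (p = 0.0575, adjusted p = 0.108). Among them, in order of coordinate, TRUE came before FALSE in 55.0% (95% interval 48.2 to 61.6%; exact binomial test, p = 0.166). Pairs in a run share domains, and changes of direction along a run must alternate. The pairs are therefore not independent trials, and the intervals and p-values of both pair tests are approximate.

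The typical class 1 domain was as long as the typical class 0 domain, but domains above 1000 kb or up to 250 kb were less often in class 1 than those between 250 and 500 kb. The median length was 400 kb in both classes, with quartiles of 300 and 550 kb in class 1 and 300 and 600 kb in class 0. The difference of medians was 0 kb (95% interval -25 to 25 kb; permutation test, p = 1). An observed difference of 0 gives this p-value whatever the lengths, and medians tie easily on the 25 kb grid. The p-value is therefore no evidence of equal lengths. The means differed, at 505 kb in class 1 and 553 kb in class 0, a difference of -48.0 kb (95% interval -76.9 to -18.8; permutation test, p = 0.00278, adjusted p = 0.00695). The class 1 share was 31.3% (28.1 to 34.7%) for domains of up to 250 kb, 38.3% (36.2 to 40.4%) between 250 and 500 kb, 34.1% (31.2 to 37.2%) between 500 and 1000 kb and 28.1% (23.7 to 32.9%) above 1000 kb. The share differed between these 4 groups (permutation test, p = 7e-05, adjusted p = 0.000262). Against the group between 250 and 500 kb the difference was -7.0 percentage points up to 250 kb (Fisher's exact test, two-sided, p = 0.000659) and -10.2 above 1000 kb (Fisher's exact test, p = 0.000182). This reference group had the highest share of the 4, which favours small p-values in both tests. The group between 500 and 1000 kb was not tested against it. Within class 1 the median length was 400 kb for both directions (95% interval of the difference, TRUE minus FALSE, -50 to 0 kb; permutation test, p = 1). Here too the p-value was fixed by the tie. With tuned edges the class 1 medians were 320 kb for TRUE and 350 kb for FALSE, a difference of -30 kb (permutation test, p = 0.0866).

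**Figure D3:**
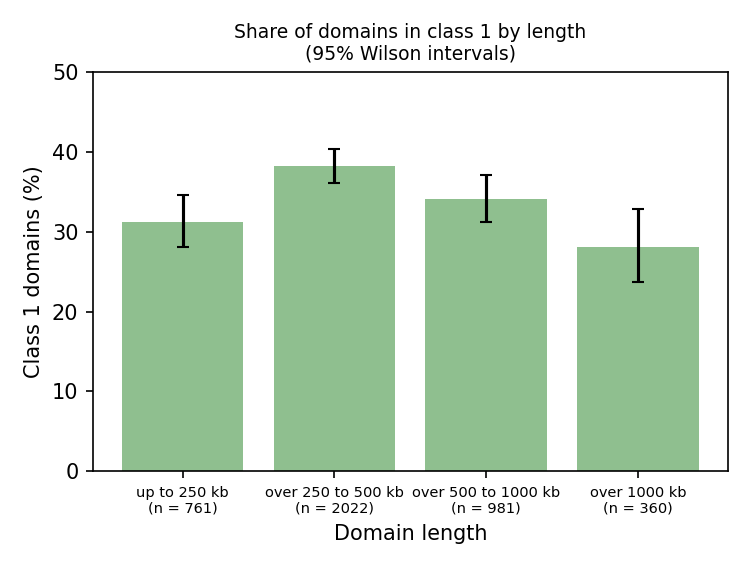
Bars give the percentage of domains in class 1 for 4 groups of domain length in kb, with 95% Wilson intervals and the number of domains under each bar. The share is highest, 38.3%, between 250 and 500 kb and lowest, 28.1%, above 1000 kb.

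The longest class 1 domain was on chromosome 3 from 22175001 to 26975000, with a length of 4800 kb, direction TRUE and a probability of 1.00. It was followed by domains on chromosome 14 from 81250001 to 84800000 (3550 kb, TRUE, probability 1.00) and on chromosome 8 from 98450001 to 101975000 (3525 kb, TRUE, probability 0.94). The next were 2 domains of 3300 kb with direction FALSE on chromosome 6, from 61300001 to 64600000 (probability 0.69) and from 108775001 to 112075000 (probability 1.00). The longest domain of all, on chromosome 1 from 100550001 to 106875000, was 6325 kb long and in class 0, with a probability of 0.13.

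The direction of a domain went with the position of its tuned edges. In class 1 domains of direction FALSE, the tuned start lay on average 35.4 kb inside the domain (SE over domains 0.897, n = 744) and the end 25.3 kb (SE 0.902). In class 1 domains of direction TRUE, the start lay 24.6 kb inside (SE 0.956, n = 704) and the end 36.1 kb (SE 0.881). The start shift minus the end shift was thus -11.6 kb in TRUE and 10.0 kb in FALSE domains, a difference of -21.6 kb (95% interval -25.1 to -18.1; permutation test, p = 1e-05, adjusted p = 5e-05, with p the smallest these permutations can give). Class 0 domains had the same sign and a smaller difference, -8.79 kb (95% interval -11.2 to -6.45; permutation test, p = 1e-05). The difference between the classes was -12.8 kb (95% interval -17.0 to -8.75; permutation of class within direction, p = 0.0001, the smallest those permutations can give). In medians the difference between directions was -20 kb in class 1 (95% interval -25 to -17.5 kb) and -10 kb in class 0 (-10 to -5 kb). The classes then differed by -10 kb (-20 to -7.5 kb; permutation of class within direction, p = 0.0272).

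The direction also went with the lengths of the neighbouring domains. In class 1 domains of direction FALSE, the upstream neighbour averaged 558 kb (SE 17.6) and the downstream neighbour 491 kb (SE 17.6). In class 1 domains of direction TRUE, the upstream neighbour averaged 495 kb (SE 20.6) and the downstream neighbour 596 kb (SE 21.9). The mean downstream minus upstream length differed by 168 kb between TRUE and FALSE (95% interval 92.6 to 240.2 kb over 1433 domains; permutation test, p = 1e-05, adjusted p = 5e-05). In class 0 this difference was 52.6 kb (95% interval 2.22 to 102 kb; permutation test, p = 0.0397, adjusted p = 0.085). The classes differed by 114.96 kb (95% interval 26.8 to 203 kb; permutation of class within direction, p = 0.009). In medians the difference between directions was smaller, 100 kb in class 1 (95% interval 75 to 150 kb; permutation test, p = 0.0001) and 50 kb in class 0 (0 to 50 kb; permutation test, p = 0.0071). The classes then differed by 50 kb (25 to 125 kb), which the permutation of class within direction did not call (p = 0.109).

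**Figure D4:**
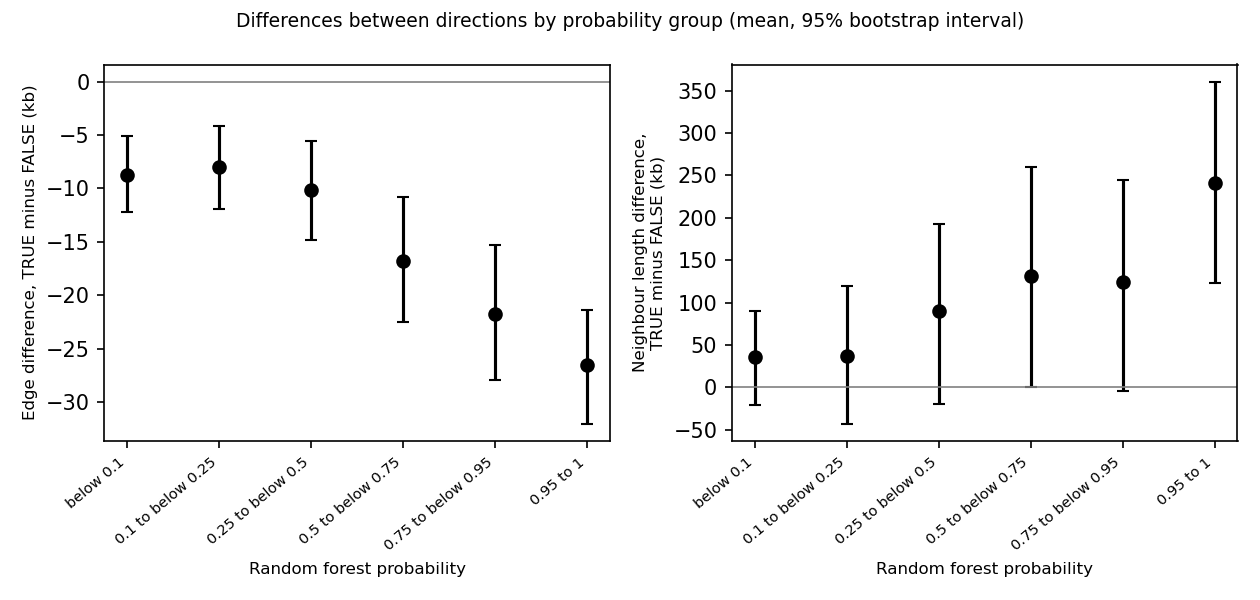
For 6 groups of random forest probability, the left panel gives the start shift minus the end shift (kb) in TRUE minus FALSE domains, and the right panel the downstream minus upstream neighbour length (kb) in TRUE minus FALSE domains; points are differences of means and lines 95% bootstrap intervals. The left values go from -8.72 kb below a probability of 0.1 to -26.6 kb at 0.95 or more, and the right values from 36.1 to 241 kb. The right values do not rise steadily, with 132 kb at 0.5 to below 0.75 and 124 kb at 0.75 to below 0.95. The interval of the latter (-4.50 to 245 kb) and those of every group below 0.5 span both signs.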

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

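The table gives no values per library, so leaving out a library was not possible, and no depth could be set against any call. No paired analysis was possible because there is 1 group in 1 table. Alternatives that used the low-imbalance set, tuned edges, means, merged neighbours or touching neighbours were chosen after seeing the data, as were all alternatives of the neighbour, edge, length group and gap results. Of 110 alternatives with a test, 76 of which left out 1 chromosome, 101 kept the side of the threshold and any sign the reported value had. That tally leaves out 6 settings that could not move a value (overlaps merged, repeated coordinates, autosomes only, reciprocal overlap and log10 of 2 length differences of 0), and values without a test. Keeping class 1 domains with a probability of 0.89 or more left 789 domains with a median length of 425 kb, and 0.99 or more left 445 with a median of 425 kb. Both counts follow from the stricter threshold itself. Tuned edges gave a median class 1 length of 330 kb. They lay inside the domain, on average by 30.1 kb at the start and 30.6 kb at the end of class 1 domains. Why the tuning moved them inward is not given in the sources used here. The length difference between classes was called for means (-48.0 kb, permutation test, p = 0.0035) and not for medians, with tuned edges giving -10 kb (p = 0.752). The difference of median lengths between directions in class 1 was -30 kb with tuned edges (permutation test, p = 0.0866) and -12.5 kb with the low-imbalance set as class 0 (permutation test, p = 0.18), neither called. The excess of neighbouring class 1 pairs over the permuted mean, 0.36%, was never called and its sign was not stable. It was -1.26% with the low-imbalance set as class 0, -0.023% with classes permuted over all chromosomes, and -0.30%, -0.42%, -0.68%, -0.030%, -0.37% and -0.21% without chromosome 5, 6, 10, 11, 12 or 15. At a probability of 0.99 or more the excess was 26.2% (permutation test, p = 0.101). Leaving out each of the 19 chromosomes kept the edge difference between -22.5 and -20.8 kb, the neighbour difference between 151 and 211 kb and the TRUE share between 47.8 and 49.0%. The density ratio of the highest to the lowest chromosome was 1.61 by number and 1.54 by bases covered, each between the extremes of 19 chromosomes under its own measure, and the class share over all chromosomes gave no call (permutation test, p = 0.248). Overlap of class 1 domains was 0% at both overlap criteria. Circular shifts were not run, since they keep every distance between domains. Other settings for gene starts, gene lists and CTCF motifs were not run either, since those comparisons were not made.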

Other observations

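A few very short domains had the most extreme imbalance. The highest imbalance score, 4.77, belonged to a class 1 domain of 50 kb on chromosome 12 from 20050001 to 20100000. The next, 3.49, belonged to a class 1 domain of 100 kb on chromosome 4 from 60525001 to 60625000. A class 0 domain nearby, from 60400001 to 60500000, was 1 of 2 with an infinite imbalance and no probability, the other being on chromosome 7 from 32600001 to 32800000. Probabilities were also strongly tied: 359 domains shared the value 0.13.

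All tests below were chosen after the table had been seen, and only those of gaps were fixed before their own results were seen. The first pattern is the set of 92 class 1 domains with an imbalance under 0.2, far below the other class 1 domains. Very short domains as the whole source are argued against by their lengths, since 25.0% were 250 kb or shorter, against 25.6% of the 270 class 0 domains in the same imbalance range (a difference of -0.56 percentage points, 95% interval -10.8 to 9.97). The share among the other class 1 domains was lower, 15.9%, so a part played by short domains stays open. All 92 lay close to the threshold of 0.5, with probabilities of 0.50 to 0.62. Of the 362 domains in their imbalance range, 25.4% were class 1. The 480 domains below that range, all class 0, had a median probability of 0.37. The 1732 domains between that range and the other class 1 domains had a median of 0.13. The set is thus the part of a wider rise in probability at low imbalance that reached the threshold. Whether a narrow majority of the classifier's votes is the source could not be told from edge positions. The edge difference between directions in the 92 domains was -9.78 kb (95% interval -22.7 to 2.83). That range holds both the -8.79 kb of class 0 and the -22.4 kb of the other class 1 domains. That test replaced an earlier one by probability, dropped because it restated how the set had been seen. No biological explanation was tested, because the design has 1 group.

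The second pattern is the edge difference of -21.6 kb between directions in class 1. If tuned edges went with direction equally in every domain, class 0 should show as much, provided that its directions are as reliable. The class 0 difference was -8.79 kb and lay apart from class 1 by more than its interval. How reliable direction is in class 0 is not given in the sources used here. The median imbalance score was 0.203 in class 0 against 0.704 in class 1. Less reliable directions in class 0 could alone shrink its difference, so the contrast does not decide this explanation. In medians the classes differed by -10 kb (95% interval -20 to -7.5 kb; permutation of class within direction, p = 0.0272). The part of the difference that class 0 shares may still come from the tuning itself. Gaps beside the domains were argued against as the whole source, because class 1 domains with a touching neighbour on both sides (783 domains) kept a difference of -16.6 kb (95% interval -20.9 to -12.2). A contribution of gaps to part of the difference stays open, since this interval does not reach the full -21.6 kb. Class 1 domains also bordered gaps more often than class 0 domains (45.5% against 40.0%). The contrast with class 0 was not repeated among touching domains, so it was not separated from gaps. A link built in by how direction, edges and probability were computed from the same contacts stays open too.

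The third pattern is the mean neighbour length difference of 168 kb, in which on average the longer neighbour of a class 1 domain lay downstream in direction TRUE and upstream in direction FALSE. By means class 0 gave 52.6 kb and the classes differed by 114.96 kb (95% interval 26.8 to 203 kb). In medians the classes differed by 50 kb (95% interval 25 to 125 kb) and the permutation test did not call it (p = 0.109), so this contrast rests on means. As with the edges, less reliable directions in class 0 could give this contrast. An equal difference in every domain therefore stays open, as does the part that class 0 shares. Gaps were argued against as the whole source by a difference of 180 kb (95% interval 63.9 to 294) where both neighbours touched, which leaves a contribution to part of it open. Since the side that TRUE names is not given in the sources used here, whether the longer neighbour lies at the stripe's anchor or at its far end could not be told, and a direction score that also reads contacts with the neighbours may give the same pattern.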
